A study of Mus musculus with 2 samples.

How the data were processed

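Mouse liver at embryonic day 13.5 was measured by ATAC-seq in 2 libraries of 1 group, numbered by the submitters as biological replicates 1 and 2. Per the labels, both came from pooled male and female B6NCrl embryos and were tagmented with the Nextera transposase. The files deposited for each library and for the series are peak lists on the mm10 assembly. They comprise lists ranked by the irreproducible discovery rate (IDR), lists thresholded on it, pseudoreplicated lists and, for the pool of both libraries, replicated, conservative and optimal lists, named so in the text deposited with the samples. The aligner, the peak caller, their versions and any filter on repeated regions are not given in the sources used here.

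The signal value of each entry was computed and deposited by the authors, and what it is relative to is not given in the sources used here, so it was compared by rank or ratio and used otherwise only within a list. The −log10 p of each entry was likewise computed by the authors and deposited with the peak, and it was used in alternatives, once in the description of the beta-globin cluster, and in the closing section. The score of each entry in the deposited IDR lists is the authors' scaled IDR, since it matched the value computed from the IDR column within 1 unit in every entry of the ranked lists, and a score of 540 corresponds to an IDR of 0.05. Read counts and alignments were not used here, so the depth of each library is unknown and the precision of a single peak cannot be given. No entry lay past the end of a chromosome of the reference.

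Entries are summits, and entries that overlap were merged into regions. For the overlap given by chance, regions were placed at random with bedtools 2.31.1. The main list was the optimal IDR-thresholded list of the pool, and each library's own thresholded list stood beside it. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The annotation was the basic set of GENCODE M21 with 21911 protein-coding genes. A summit within 1000 bp of any annotated start site, coding or not, was called promoter, and the other summits, called distal, were exonic, intronic or intergenic. A distal summit was assigned to its nearest protein-coding start within 100000 bp.

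A summit was shared when its peak overlapped one of the other library by at least 1 bp, and 100 random placements on the same chromosome gave the share and the locations that chance gives. Signal agreement was computed on log2 values of pairs of summits, 1 from each library, that were each other's nearest and whose peaks overlapped. No p-value was attached to the overlap or the signal agreement of the 2 libraries, the tests of library-only summits and of signal ranks compare summits within these libraries and not samples, and no outlier test applies.

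Before the data were examined, 18 gene lists, 22 consensus motifs and the tests were fixed. The lists were globins, erythroid regulators and receptors, red cell membrane, heme synthesis, hepatoblast and fetal hepatocyte, coagulation factors, mature hepatocyte metabolism, blood stem and progenitor, megakaryocyte, myeloid and macrophage, lymphoid, endothelial, stellate and mesenchymal, bile duct, neuronal, muscle and heart, housekeeping, and olfactory receptors. Of the listed symbols, 3 were absent from the annotation (Hbb-b1, Hbb-b2 and Ahsp). The erythroid and red cell membrane lists share 2 genes, and the stem and megakaryocyte lists share 1.

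Promoter shares of lists and library-only peaks were tested with Fisher's exact test, two-sided, and distal summits with a two-sided permutation test of 100000 random gene sets drawn within 10 bins of territory, the distance between neighbouring start sites. The smallest p this permutation can give is 2e-05. Motifs were searched on both strands within 100 bp of the summit and tested with Fisher's exact test against windows 2000 bp to either side that overlap no peak of any list, sampled to the same GC content in bins of 2 percent. Summits left without a flank in the same GC bin were dropped from this comparison. Motifs were also compared between the 25% of distal summits with the highest and the lowest signal. P-values were adjusted by Benjamini-Hochberg within each set of lists or motifs at a threshold of 0.05. Odds ratios have 0.5 added to each count, with 95% Woolf intervals. Genes and summits are not biological replicates, and neither summits of one region nor neighbouring genes of one cluster are independent, so each p describes these pooled libraries.

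Tests were checked on simulated data. Distal counts raised 2-fold were called in 7 of 10 simulated lists and counts raised 4-fold in 10 of 10, with 0 of 100 unchanged lists called. Promoter shares of 0.1 and 0.9 were called in 8 and 10 of 10 lists, and planted motifs in 5 of 5 cases, with 1 of 16 unplanted motifs called.

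Named genes followed a rule set in advance. From each list up to 4 members with the most distal summits and up to 3, in list order, without a promoter summit were named. Also named were the 10 summits of highest signal, the 10 genes with the most distal summits, the 5 strongest library-only summits of each library, and up to 5 summits in each of 9 loci with 100000 bp on either side. Gata1, Klf1 and Tal1 as members of the erythroid promoter count, and the promoter signal of Klf1, were chosen after the values were seen. So were the globin genes named as having a promoter summit, with their signals.

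Alternatives were promoter windows of 500 and 2500 bp, motif windows of 50 and 200 bp, flanks not matched on GC, other matching and assignment of distal summits, the conservative, replicated and pseudoreplicated lists, an IDR of 0.01, other definitions of a shared summit, the −log10 p in place of the signal, and each library alone. Merged regions, 1 summit per merged region, and GC matching in the strength comparison were added later. All chromosomal entries of the main lists were used, and no sample was left out.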

Results

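Chromatin accessibility was measured by ATAC-seq in the liver of mouse embryos at embryonic day 13.5. In this assay a transposase inserts sequencing adapters into DNA that is not packed around nucleosomes, so that fragments accumulate at open promoters and enhancers. At this stage the liver is the main site of blood formation, and it holds large numbers of erythroid precursors beside hepatoblasts, the progenitors of hepatocytes and bile duct cells. The tissue came from B6NCrl embryos of both sexes, pooled. The samples formed 1 group of 2 libraries, which the submitters number as biological replicates 1 and 2 and which are called library 1 and library 2 here. With a single group there was no comparison of conditions, and the design allowed the 2 libraries to be set side by side and the accessible regions of the pooled data to be described.

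The data are called peaks on the mm10 build of the mouse genome, without read counts, so the sequencing depth of each library is unknown. Each entry of a peak list is a summit with its own signal value, given by the authors, and several summits can lie in one region. The pooled list, thresholded by the authors on the irreproducible discovery rate, held 61085 summits in 29314 regions that covered 21.5 Mb. Library 1 had 49490 summits in 23816 regions and library 2 had 45593 summits in 22387 regions, a mean of 47541.5 ± 2755.6 summits (SD, n = 2). The regions had a median length of 691 bp, and 60.9% of them held more than 1 summit.

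Promoters made up the most frequent class of accessible site. Of the pooled summits, 33004 (54.0%, exact 95% interval 53.6 to 54.4%) lay within 1000 bp of an annotated transcription start site, against 4.55% of randomly placed summits, which is 11.9-fold more. The share was 59.7% in library 1 and 61.0% in library 2. Introns held 27.4% of the summits, intergenic DNA 16% and exons 2.57%, each below the share of randomly placed summits (42.3%, 50% and 3.12%). With 1 summit kept per region, the promoter share was 41.8%, and in replicated peaks the exon share, 3.76%, was above that of the randomly placed summits. The gene-dense chromosome 11 carried 38.6 summits per Mb and the X chromosome 9.26 per Mb, with 20 summits on the Y chromosome.

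The single strongest summits of the pooled list were not at protein-coding promoters. The highest signal, 58.5 (58.2 in library 1 and 55.3 in library 2), was at chromosome 2, 69355469 to 69355735, in intergenic DNA 12988 bp from the start of Abcb11, which encodes the bile salt export pump of hepatocytes, and its summit carried a GATA motif. The next was intergenic on chromosome X, 143482935 to 143483180, 35531 bp from Pak3, a kinase gene of the nervous system, with a signal of 57.9. The third, 49.9, lay on chromosome 1, 102628104 to 102628398, far from any gene, at 2140260 bp from the cadherin gene Cdh20. A summit in an intron of Gnb1l on chromosome 16 had a signal of 48.3, with Rtl10 as its nearest coding start. The remaining members of the top 10 had signals of 39.1 to 47.2 and were nearest to G6pd2, Epm2a, Gm5426, Frmd4a, Myl12b and Hic2, all of them intronic or intergenic. Each of the 10 summits was found in both libraries.

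Genes with the most distal summits, those more than 1000 bp from any start site and within 100000 bp of their nearest coding start, included the erythroid regulator Sox6 beside genes of general function. Pde4d, a cyclic AMP phosphodiesterase on chromosome 13 (108449948 to 109953461), had 31. Mbp, which is known for myelin and also has a transcript made in blood cells, had 29. Sox6, a repressor of embryonic globin genes, and Sgms1, a sphingomyelin synthase, had 27 each. Macf1, which links actin to microtubules, had 25 although none of its annotated starts had a promoter summit. Zfp217, Cd24a, Podxl, Nol4l and Iqsec1 followed with 24 each, among them Cd24a, a surface protein of erythroid precursors, and Podxl, a sialomucin of early blood cells and endothelium. These counts were not adjusted for territory, the distance between neighbouring start sites, which was 1.27e+06 bp for Pde4d and 119866 bp for Cd24a. Several summits can also share a region, and those of Pde4d lay in 19 regions and those of Macf1 in 11.

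The 2 libraries were compared first by position. Of the library 1 summits, 43919 (88.7%) overlapped a region of library 2 by at least 1 bp, and 42352 (92.9%) of the library 2 summits overlapped a region of library 1, whereas regions placed at random on the same chromosome gave 1.45% ± 0.0811 (SD, 100 placements). The covered bases had a Jaccard index of 0.741. Over 38630 pairs of mutually nearest summits with overlapping peaks, the log2 signal had a Pearson r of 0.970 and a Spearman rho of 0.973. These correlations are across summits within 2 libraries, summits are not independent replicates, and no p-value was attached. The median ratio of signal, library 1 over library 2, was 1.06, 90% of ratios lay between 0.817 and 1.39, and 0.135% of pairs differed by more than 2-fold.

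**Figure D1:**
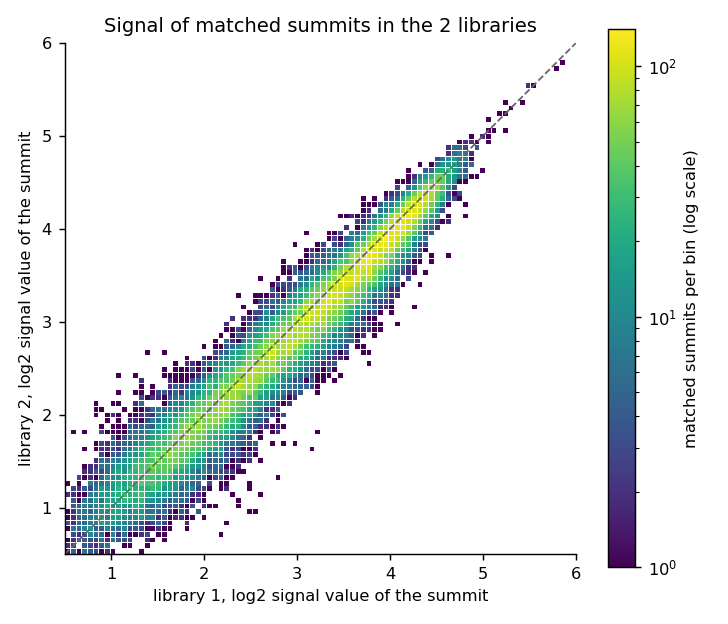
Log2 signal value of matched summits in library 1 (x axis) and library 2 (y axis), coloured by the number of summits per bin on a log scale, with the line of equal values dashed. The 38630 pairs follow the line with a Spearman rho of 0.973, and 19 pairs fall outside the plotted range.

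Summits called in one library alone were weaker than shared ones. The 5571 summits of library 1 without a counterpart had a median signal of 5.63, against 7.18 for its shared summits, and the 3241 of library 2 had 5.75 against 6.98. Most of them were present in the less strict list of the other library, 92.7% for library 1 and 96.4% for library 2. The 5 strongest summits found in library 1 alone were at the promoters of Mum1l1 on chromosome X (signal 22.3) and Dpyd, which encodes the first enzyme of pyrimidine breakdown, and in introns or intergenic DNA nearest to Nabp1, Arl13a and Lcorl, at distances of 21144 to 1036607 bp. Those of library 2 were nearest to Gm5148 (17.1), in introns of Kif13a and Batf, at the promoter of Igsf1, and 166915 bp from Klf3 beside the start of another transcript. All 10 had a peak in the less strict list of the other library.

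Erythroid regulators and receptors more often had a promoter summit than other genes, and they had more distal summits than random gene sets. The high promoter share was not particular to them, since all 23 housekeeping genes also had a promoter summit. Among the erythroid regulators and receptors, 28 of 29 genes had a promoter summit, in each library as in the pool, against 51.2% of other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 8.16e-07, Benjamini-Hochberg over 18 lists). The master regulators Gata1, Klf1 and Tal1 were among the 28, and Gfi1b, a repressor needed for red cell and platelet formation, was the exception, with 4 distal summits. The list averaged 6.41 distal summits per gene (5.17 in library 1 and 4.55 in library 2), 5.80 times the mean of random gene sets matched on territory, the spacing of neighbouring start sites (permutation test, adjusted p = 0.00012, from the smallest p that 100000 sets can give). Sox6 on chromosome 7 (115470872 to 116038796) had 27 distal summits, with signals of up to 25.1. Zfpm1, the cofactor of Gata1, had 19, and Cbfa2t3, a corepressor of the Tal1 complex, and Foxo3, which controls antioxidant genes in maturing red cells, had 14 each.

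The proteins that shape the red cell membrane showed the same pattern. In that list 19 of 20 genes had a promoter summit (95% in each library, exact test, adjusted p = 0.000113), and all 20 had at least 1 distal summit, with a mean of 7.25 per gene, 5.36 times that of matched random sets (permutation test, adjusted p = 0.00012). Cd47, the signal that protects red cells from phagocytosis, had 16 distal summits, and Ank1, the anchor of the spectrin skeleton, had 14. Aqp1, the water channel, had 15 and was the gene without a promoter summit, and Gypc, a glycophorin, had 11. All 9 enzymes of heme synthesis had a promoter summit in the pool and in library 1, and 88.9% of them in library 2 (exact test, adjusted p = 0.00553), with 2.78 distal summits per gene, 3.51 times the random mean (permutation test, adjusted p = 0.0282). Fech, which inserts iron into the ring, had 8. Alas2, the erythroid form of the first enzyme, had 5, with a signal of up to 26.5, and Cpox and Alad had 3 each.

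Globin genes had distal summits more than promoter summits. Of the 10 annotated globin genes, 4 had a promoter summit, a share that did not differ from other genes (40.0%, exact 95% interval 12.2 to 73.8%, adjusted p = 0.607), while 8 had a distal summit and the mean of 2.30 per gene was 7.79 times that of random sets matched on territory (permutation test, adjusted p = 0.00018) but 2.00 times that of random sets without this matching (0.311). The embryonic gene Hbb-y, the theta-like gene Hbq1a and the adult gene Hbb-bs had 4 distal summits each and the adult gene Hbb-bt had 3. Those of Hbb-y lay in 4 regions and those of Hbq1a in 3. The 4 of Hbb-bs lay in 1 region, 1240 to 2108 bp from its start, and the 3 of Hbb-bt in 1 region. With 1 summit per region the list averaged 1.20 distal summits per gene, 6.76 times matched random sets. The globin genes lie side by side in the beta-globin and alpha-globin clusters but were counted as independent genes, so the permutation p-values can be too small. The 4 genes with a promoter summit were the adult genes Hbb-bs and Hbb-bt and the alpha-globin genes Hba-a1 and Hba-a2, in both libraries. Their promoter signals in the pool were 11.4, 9.53, 5.75 and 8.47. Hbb-y, Hba-x, Hbq1a and Hbq1b had no promoter summit. Near-identical globin copies can share reads, and how the authors treated such reads is not given in the sources used here.

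In the beta-globin cluster the summits of highest signal lay outside the globin genes, among olfactory receptor genes, whereas the highest −log10 p were at the Hbb-bs promoter (1686.47) and in intergenic DNA nearest to Hbb-y (1644.71). The interval from Hbb-bt to Hbb-y with 100000 bp on either side held 28 summits in 19 regions, or 11.6 per 100 kb, against a genome average of 2.24, with 27 in library 1 and 25 in library 2. The highest signal, 19.2, was at chromosome 7, 103910005 to 103910483, in intergenic DNA at −56976 bp from the Hbb-y start and 3850 bp from the nearest coding start, Olfr65. The 41 bp around this summit, chromosome 7, 103910172 to 103910212, read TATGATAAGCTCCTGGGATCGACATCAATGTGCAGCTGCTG on the plus strand. A second intergenic summit on the same side, at 103915334 to 103915910, had a signal of 18.3 and carried the composite GATA and E-box motif, as did one at 103877076 to 103877496 with 15.4, nearest to Olfr66. Downstream of the adult genes, summits at 103792816 to 103793396, nearest to Olfr67, and at 103777506 to 103778248, in the coding exon of Olfr68, had signals of 17.5 each.

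In the alpha-globin cluster the strongest summits lay in the introns of Nprl3, the upstream neighbour whose body is known to hold alpha-globin enhancers. The interval from Hba-x to Hba-a2 with its flanks held 31 summits in 17 regions, 14.0 per 100 kb, with 26 in library 1 and 30 in library 2. Intronic Nprl3 summits were found at chromosome 11, 32255962 to 32256854 (signal 25), 32250737 to 32251368 (22.9) and 32245352 to 32246050 (17.6). The first lay at −20063 bp from the Hba-x start, and the 41 bp around it, 32256317 to 32256357, read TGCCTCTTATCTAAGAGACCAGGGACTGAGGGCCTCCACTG. Each of these carried a GATA motif. The promoter of Snrnp25 had a signal of 23.1, and an intergenic summit at 32269009 to 32269599, upstream of Nprl3, had 13.1.

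**Figure D2:**
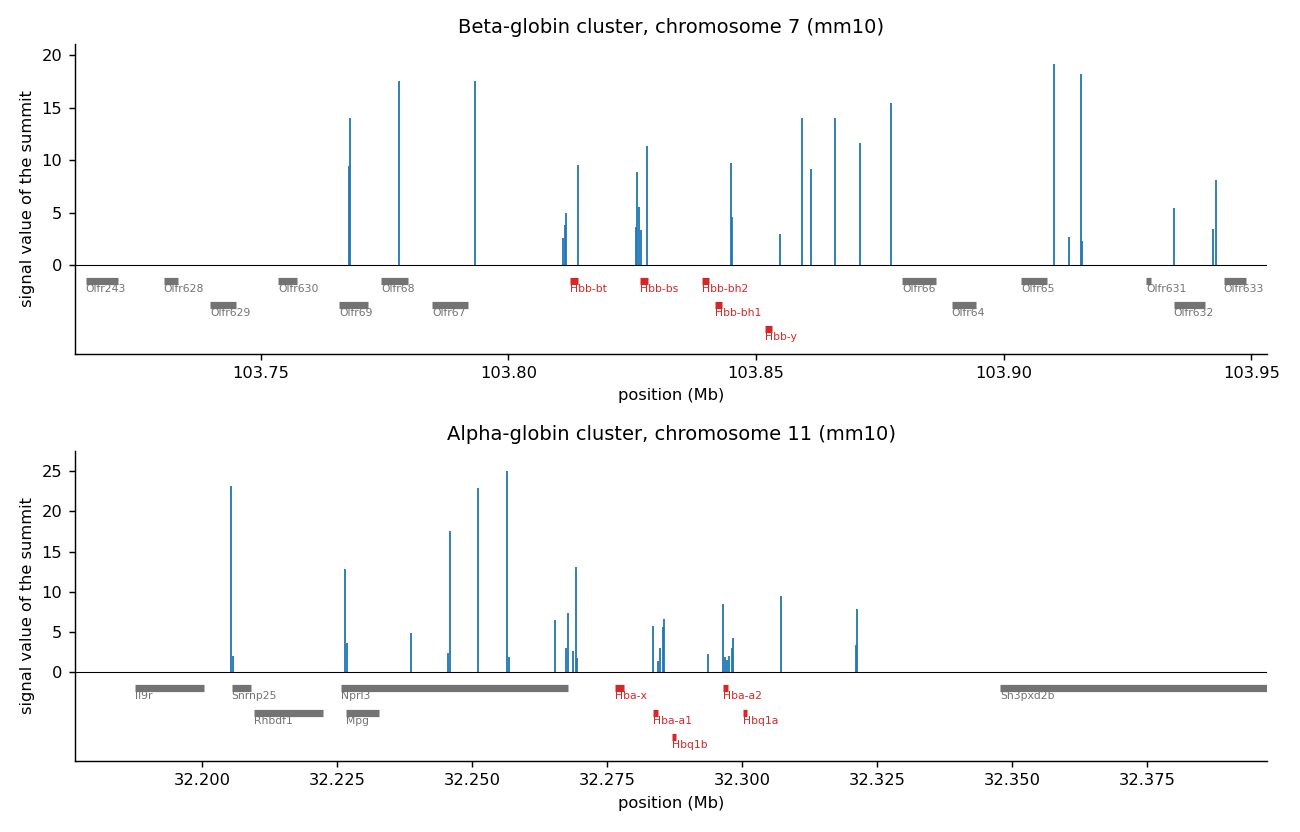
Signal value of each summit of the pooled list (blue lines, y axis) along the beta-globin cluster on chromosome 7 (top) and the alpha-globin cluster on chromosome 11 (bottom), position in Mb on mm10, with coding genes drawn as bars, globin genes in red. The highest beta-globin summit, 19.2, lies among olfactory receptor genes and the highest alpha-globin summit, 25, lies within Nprl3.

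Around the erythroid regulators the strong summits were often the promoters of neighbours. The Klf1 interval on chromosome 8 was the densest of the 9 loci examined, with 52 summits (25.6 per 100 kb), led by the promoters of Calr (signal 20) and Gcdh (19.1). Klf1 itself had a promoter signal of 8.73. The Gata1 interval on chromosome X held 22 summits, among them the promoters of Timm17b (21.4), Hdac6 (20.5), Suv39h1 (19.4) and Pim2 (16.7). It also had an intergenic summit with the composite motif at 7992786 to 7993961, with a signal of 16. This summit lay at −15417 bp from the upstream end of the annotated Gata1 gene. Its nearest coding start was that of Glod5, at 25004 bp. Around Tal1 on chromosome 4 there were 23 summits, led by the Stil promoter (21.4). An intergenic summit at 115095455 to 115096438, 39468 bp downstream of the Tal1 start, had a signal of 13.3 and the composite motif.

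Kit, the stem cell factor receptor, had no neighbouring coding gene in its interval, where 9 summits were found. The strongest were intronic, at chromosome 5, 75624029 to 75624876 (signal 14.4) and 75607894 to 75608543 (11.5), both with the composite motif, ahead of the Kit promoter at 9.20. The Gata2 interval on chromosome 6 held 20 summits, led by intergenic summits at 88116308 to 88117487 (11.9) and 88123941 to 88124288 (9) and one in an intron of Eefsec (10.1). Gata2 itself, a regulator of blood stem cells, had no promoter summit.

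The hepatoblast and fetal hepatocyte list holds secreted proteins and transcription factors of the early liver parenchyma. A promoter summit was found at 16 of 32 genes (50%), against 51.3% of other genes (exact test, adjusted p = 1). This result depends on the list, since the share was 90.6% in replicated peaks, more often open than other genes (exact test, adjusted p = 0.000466), 28.1% in library 1, less often open (0.0279), and 37.5% in library 2. Distal summits averaged 2.5 per gene (1.44 in library 1 and 1.25 in library 2), 2.13 times matched random sets (permutation test, adjusted p = 0.0282). Dlk1, a surface protein of hepatoblasts, had 14 distal summits, and the liver transcription factor genes Prox1, Hnf4a and Hnf1a had 7, 7 and 6. The 7 distal summits of Hnf4a were in the pooled list and in neither library alone. Alb, which encodes albumin, had 3 distal summits, and Afp, which encodes alpha-fetoprotein, had 5, and neither had a promoter summit. Apoa2, an apolipoprotein gene, had neither kind.

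The interval from Alb to Afp on chromosome 5 held 17 summits in 6 regions. Its strongest was intergenic, at 90447471 to 90448209, 13093 bp upstream of Alb, with AP-1 and HNF4 motifs and a signal of 12.2 (7.93 in library 1 and 14.5 in library 2). Another, at 90430961 to 90431499, 29600 bp upstream of Alb, had 9.04 and carried a FOXA motif. In the Hnf4a interval on chromosome 2 there were 28 summits, 12 in library 1 and 20 in library 2, led by the promoters of Oser1 (20.2), Fitm2 (14.3) and Ttpal (12.8).

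Coagulation factor genes had a promoter summit in 7 of 18 cases (38.9%, exact test, adjusted p = 0.449) and 1.28 distal summits per gene, 1.11 times the random mean (permutation test, adjusted p = 0.796). F5 had 6 distal summits and Plg, the plasminogen gene, Proc and Cpb2 had 3 each, whereas F7 and F9 had no summit of either kind. Genes of mature hepatocyte metabolism were less often open at their promoters than other genes, in 3 of 28 cases (10.7%, with 17.9% in library 2, exact test, adjusted p = 3.73e-05; 39.3% and 0.0572 in replicated peaks), and did not differ in distal summits (1.18 per gene, 1.08 times the random mean, adjusted p = 0.796). Fbp1 and Hpd, enzymes of gluconeogenesis and tyrosine breakdown, had 7 distal summits each, and Pah and Pck1 had 3 each. Cyp2e1 and Cyp3a11, cytochromes of the adult liver, had none, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 1.

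Blood stem and progenitor genes had a promoter summit in 12 of 21 cases (57.1%, with 33.3% in library 1 and 42.9% in library 2, exact test, adjusted p = 0.705) and 3.67 distal summits per gene, 2.33 times the random mean (permutation test, adjusted p = 0.0282). Runx1 had 15, Ikzf1 10, Fli1 9 and Myb 6, all of them transcription factors of early blood cells, and Hoxa9 and Flt3 were without a promoter summit. Megakaryocyte genes had a promoter summit in 8 of 20 cases (40.0%, adjusted p = 0.449) and 2.85 distal summits per gene, 2.99 times the random mean (permutation test, adjusted p = 0.00857). F2rl2, a thrombin receptor, and Vwf, von Willebrand factor, had 11 each, Rab27b had 8 and Mmrn1 7, while Pf4, Itgb3 and Gp1bb, which are platelet proteins, lacked a promoter summit.

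Myeloid and lymphoid genes had few promoter summits. None of 24 myeloid and macrophage genes had a promoter summit (exact 95% interval 0 to 14.2%, adjusted p = 2.85e-07), and they averaged 0.208 distal summits, 0.191 times the random mean (permutation test, adjusted p = 0.0282; 0.0833 per gene in library 1 and 0.208 in library 2). This distal call ended with promoter matching (ratio 0.355, permutation test, adjusted p = 0.342), in the conservative list (0.341, 0.142), in replicated peaks (0.6005, 0.246), in library 2 alone (0.298, 0.172), with 1 summit per region (0.315, 0.105), and with every distal summit within 50000 bp of a start counted, whichever start is nearest (0.787, 0.644). Fcgr1 had 2 and Cebpe, Cd163 and Csf1r had 1 each, while the macrophage genes Adgre1 and Lyz2 had none in the pooled list. Of 22 lymphoid genes, 4 had a promoter summit (18.2%, exact test, adjusted p = 0.00319), and the mean of 0.364 distal summits was 0.367 times the random mean (adjusted p = 0.201). Il7r, the interleukin receptor of lymphoid precursors, had 3 distal summits in 1 region with a signal of up to 23.9, and Pax5, Zap70 and Gata3 had 1 each. Cd3e, Cd3d and Cd4 had none.

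Genes of the other liver cell types and of other tissues were also less often open at promoters in the pooled list. In replicated peaks the endothelial (70%) and bile duct (62.5%) shares instead lay above that of other genes without passing (exact test, adjusted p = 0.593 and 1), and the stellate (50%) and neuronal (45.8%) calls ended (0.472 and 0.212). In the pooled list the endothelial list had 3 of 20 genes (exact test, adjusted p = 0.00194), the stellate and mesenchymal list 2 of 20 (5% in library 1, 0.000326) and the bile duct list 1 of 16 (0.000363). Among genes outside the lineage, the neuronal list had 3 of 24 (16.7% in library 1 and 4.17% in library 2, exact test, adjusted p = 0.000259), the muscle and heart list 2 of 24 (12.5% and 0%, 3.93e-05), and olfactory receptors 7 of 1134, or 0.617% (exact 95% interval 0.249 to 1.27%, with 0.353% in library 1 and 0.265% in library 2) against 54.0% of other genes. In distal summits the endothelial list had 1.24 times the random mean, the stellate list 0.401, the bile duct list 0.408, the neuronal list 0.542 and the muscle list 0.515, none past the threshold (adjusted p = 0.654, 0.178, 0.271, 0.286 and 0.271), and olfactory receptors had 0.0969 times (permutation test, adjusted p = 0.00012).

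Single members of these lists did carry distal summits. In the endothelial list Eng had 5, and Kdr, the vascular growth factor receptor, Lyve1 and Egfl7 had 4 each, with signals of up to 18.7 at Kdr, although Pecam1, Cdh5 and Kdr lacked a promoter summit. Reln had 5 and Nes, Tcf21 and Col1a1 had 2 each in the stellate list, where Des, Lrat and Pdgfrb had none in the pooled list. In the bile duct list Krt8 and Cldn4 had 3, Prom1 2 and Krt18 1, and Sox9, Krt19 and Krt7 had none. Tbr1 and Elavl4 had 4 and Gfap and Neurod6 had 3 in the neuronal list, where Neurod1 and Neurod2 had none. Ryr2 had 7, Myl7 3 and Tnnt2 and Myh3 2 in the muscle list, where Myod1, Myog and Myf5 had none. Among olfactory receptors Olfr1423 had 10 and Olfr65, which lies beside the beta-globin genes, Olfr761 and Olfr414 had 4 each, and 1098 of the 1134 had no summit of either kind.

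Housekeeping genes, which are active in nearly every cell, had a promoter summit in 23 of 23 cases (exact test, adjusted p = 1.24e-06) and 1.87 distal summits per gene, 2.41 times the random mean (permutation test, adjusted p = 0.0306), led by Ywhaz with 14, Actb and Ubc with 7 and Hprt with 4. The globin, heme synthesis and housekeeping distal calls need the territory matching, without which the heme synthesis ratio was 2.42 and the housekeeping ratio 1.64 (permutation test, adjusted p = 0.202 and 0.311). When random sets were also matched on having a promoter summit, the ratios of heme synthesis (2.55), hepatoblast (1.92), stem cell (1.76) and housekeeping genes (1.68) no longer passed (permutation test, adjusted p = 0.0820, 0.0708, 0.139 and 0.202). The hepatoblast ratio was 1.78 in the conservative list, 1.98 with 1 summit per region, 1.72 in library 1 and 1.69 in library 2, and did not pass in any of these (permutation test, adjusted p = 0.142, 0.0612, 0.201 and 0.2235). The housekeeping ratio was 1.95 in the conservative list, 1.86 in replicated peaks, 2.05 in library 1 and 2.17 in library 2, without passing (permutation test, adjusted p = 0.147, 0.0762, 0.188 and 0.137). With every distal summit within 50000 bp of a start counted, whichever start is nearest, the heme synthesis ratio was 1.77 (permutation test, adjusted p = 0.226). Mean distal summits were lower in library 1 and library 2 than in the pool for coagulation (0.722 and 0.5), mature hepatocyte (0.75 and 0.714), lymphoid (0.364 and 0.227), endothelial (0.8 and 0.75), stellate (0.45 and 0.25), bile duct (0.375 and 0.313), neuronal (0.75 and 0.583), muscle (0.333 and 0.25) and housekeeping genes (1.13 and 1.09), except lymphoid genes in library 1.

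**Figure D3:**
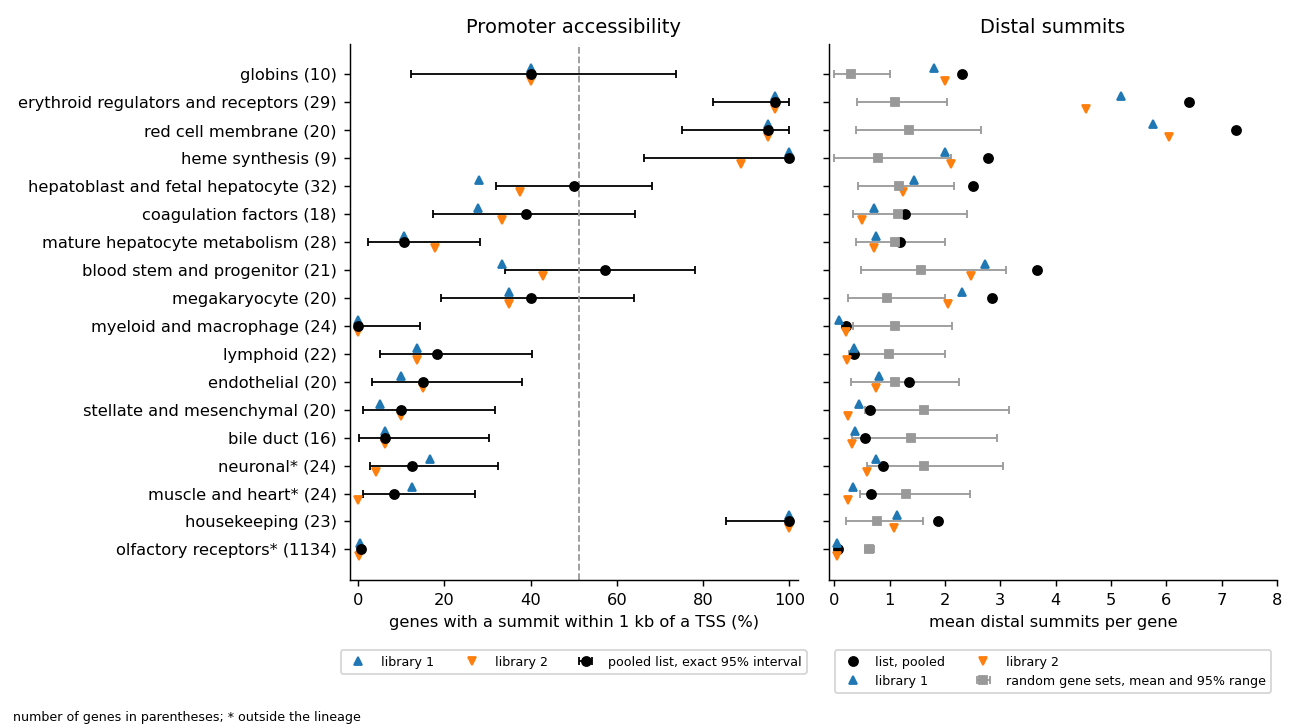
Left, percent of the genes of each list with a summit within 1000 bp of a start site, in the pooled list (black, with exact 95% interval), library 1 and library 2 (triangles), the dashed line marking all other protein-coding genes. Right, mean distal summits per gene in the pool and each library beside matched random gene sets (grey, mean and 95% range); the erythroid and red cell membrane lists have 6.41 and 7.25 per gene.

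Sequence motifs of erythroid regulators were more frequent at distal summits than in flanking DNA. GC matching kept 25028 of 28081 distal summits. A GATA site lay within 100 bp of 58.3% of 25028 distal summits, against 23.3% of flanking windows of the same GC content (odds ratio 4.60, 95% interval 4.43 to 4.78). The composite of an E-box and a GATA site, bound by the Tal1 and Gata1 complex, was in 8.42% against 0.547% (odds ratio 16.6, 95% interval 14.0 to 19.8). NFE2 sites were in 1.68% against 0.212% (odds ratio 7.98), KLF sites in 16.1% against 9% (1.95) and plain E-boxes in 30.4% against 27.8% (1.14). The CTCF consensus, which marks insulators and loop anchors, was in 1.41% against 0.172% (odds ratio 8.23). All of these passed Fisher's exact test after adjustment over 22 motifs. With 1 summit per region the GATA odds ratio was 8.38 and that of the composite 25.1.

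Motifs of hepatocyte factors were also above the flanks. CEBP sites were in 0.384% of distal summits against 0.108% (odds ratio 3.52, with 2.26 in library 1 alone), FOXA sites in 5.81% against 3.69% (1.61) and HNF4 sites in 0.811% against 0.507% (1.60), and the HNF1 site was in 18 summits against 1 flank (12.3, 95% interval 2.34 to 65.2, with 19.0 in library 2 alone). AP-1 (2.04), SP1 (odds ratio 1.965), ETS (1.71), MEF2 (1.58), PU.1 (1.28) and RUNX (1.25) were higher as well, SOX was lower (0.888), and NFY, TEAD, POU, NRF1 and REST did not pass (adjusted p = 0.0866, 0.214, 1, 0.0799 and 0.128, exact test). Against flanks not matched on GC the FOXA and MEF2 odds ratios turned to 0.988 and 0.804. In library 1 alone the HNF4 (exact test, adjusted p = 0.248), HNF1 (0.0809) and MEF2 (0.340) calls ended, as did MEF2 in library 2 alone (0.0674) and within 50 and 200 bp (0.0822 and 0.0585), RUNX within 200 bp (0.0862), and SOX within 200 bp and in replicated peaks (0.760 and 0.209). NRF1 passed as higher in each library alone (exact test, adjusted p = 0.0190 and 0.0161), within 200 bp (0.00713), without GC matching (8.54e-10) and in the conservative and replicated lists (0.00540 and 0.000420), and NFY as lower in those 2 lists (0.0126 and 0.00344) and without GC matching (2.95e-22), while TEAD, POU and REST passed as lower in some alternatives.

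At promoters another set of motifs led among the summits that GC matching kept, 12110 of 33002 searched. The GC-matched shares and odds ratios do not describe the promoter summits that were left out. Of 12110 promoter summits with a flank of matching GC, NRF1 sites were in 0.438% against 0.0248% (odds ratio 15.3, 95% interval 5.20 to 45.3), ETS sites in 2.44% against 0.314% (7.84) and SP1 sites in 19.9% against 7.20% (3.19), motifs that are common in promoters of broadly expressed genes. The NRF1 odds ratio was 89.4 in library 1 alone and 28.5 in library 2 alone, and the ETS ratio 9.40 and 12.3. In the pool the NRF1 ratio rests on 53 summits against 3 flanks. The NRF1 share of summits was 0.435% in library 1 alone and 0.461% in library 2 alone. With so few sites in flanks, the size of these NRF1 ratios is uncertain and does not rank the libraries. The composite GATA motif (3.45), CTCF (2.65), POU (2.41), NFE2 (1.83), GATA (1.57), FOXA (1.48), NFY (1.43), KLF (1.33) and PU.1 (1.25) were also higher. E-boxes (0.699), RUNX (0.879) and SOX (0.773) were lower, and AP-1, HNF4, HNF1, CEBP, TEAD, MEF2 and REST did not pass the exact test after adjustment. Promoter summits had a mean GC content of 62.9% and their flanks 44.4%. Without GC matching the odds ratios of GATA (0.383), FOXA (0.390), NFY (0.910) and POU (0.664) turned below 1, and the PU.1 ratio was 0.976 within 200 bp of the summit. The SOX call ended within 50 and 200 bp, in replicated peaks, in library 2 alone and with 1 summit per region (exact test, adjusted p = 0.566, 0.309, 0.0580, 0.339 and 0.175), RUNX in replicated peaks and with 1 summit per region (0.0701 and 0.685), NFE2 within 200 bp and in library 2 alone (0.289 and 0.140), and PU.1 in library 2 alone and with 1 summit per region (0.282 and 0.0920). Replicated peaks called AP-1, HNF4, HNF1 and CEBP higher (exact test, adjusted p = 0.000325, 0.00287, 9.56e-05 and 0.00117), CEBP passed also in the conservative list, within 200 bp and in library 1 alone (0.0189, 0.0123 and 0.0232), and AP-1 within 50 bp and with 1 summit per region (0.000132 and 6.19e-05), while TEAD and REST passed as lower in some alternatives.

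Strong distal summits carried GATA motifs more often than weak ones. Of the 7020 distal summits with the highest signal (25% of them), 77.5% had a GATA site, against 31.3% of the 7020 with the lowest signal (odds ratio 7.58, 95% interval 7.03 to 8.17), and 16.9% against 1.31% had the composite motif (15.2, 95% interval 12.3 to 18.9). NFE2 (odds ratio 5.97), NRF1 (9.68, from 14 summits against 1, with 21 in library 1 and 13 in library 2 alone), KLF (2.09), AP-1 (1.98), ETS (1.89), SP1 (1.87), CTCF (1.70), E-boxes (1.35) and RUNX (1.28) were higher too, and TEAD (0.673), SOX (0.684) and REST (0.403) were lower (exact test). With 1 summit kept per region, GATA (3.35), the composite GATA with E-box (4.17) and the plain E-box stayed higher, CTCF turned to 0.271 and FOXA to 0.733, HNF4 became lower (0.2496, exact test, adjusted p = 1.32e-06), and all other calls ended, including those for TEAD, SOX and REST (0.671, 0.280 and 0.884). The TEAD, SOX, REST, ETS and CTCF calls also ended in each library alone, as did RUNX and NRF1 in library 2 alone, the ETS call ended with GC matching (exact test, adjusted p = 0.0515), and HNF4 was lower in library 1 alone (0.505, 0.0429) and by −log10 p (0.464, 0.00504).

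**Figure D4:**
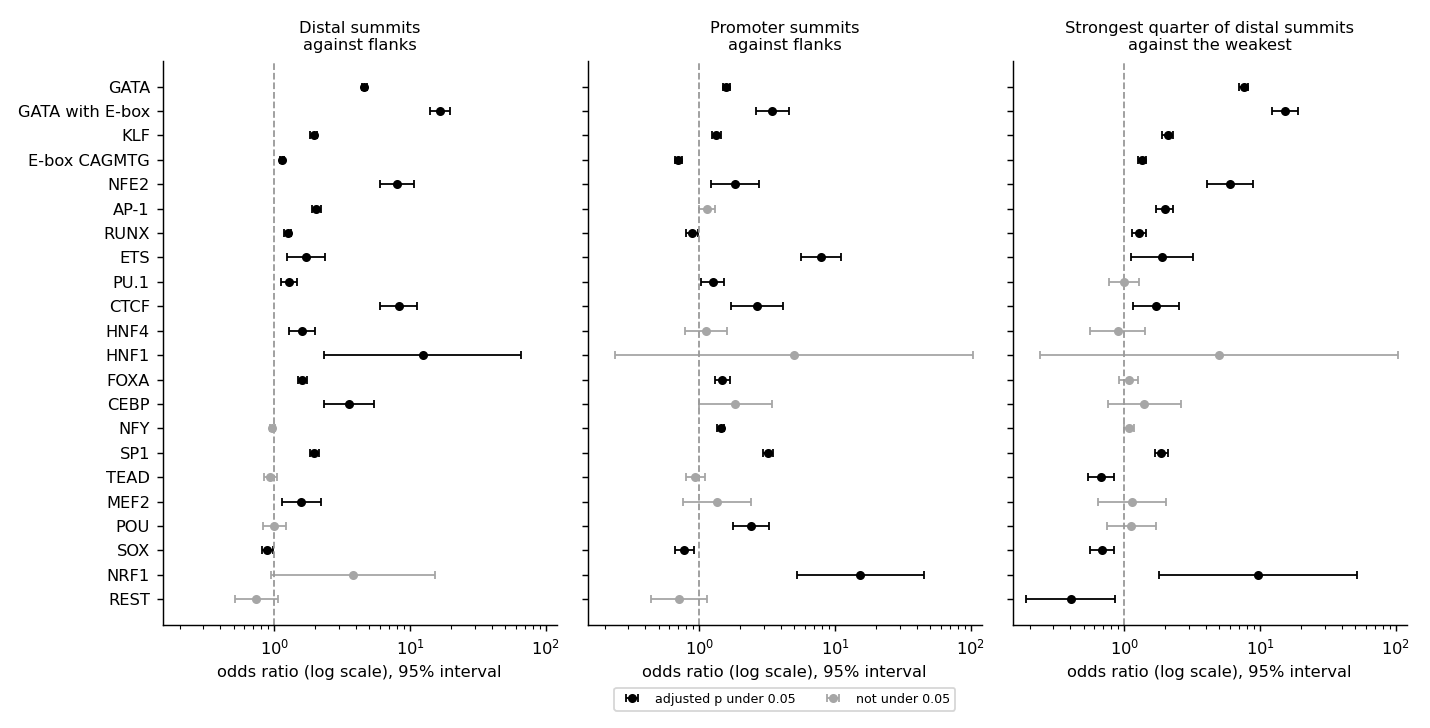
Odds ratios with 95% intervals (x axis, log scale) of 22 motifs in distal summits against flanks (left), promoter summits against flanks (middle) and the strongest 25% against the weakest 25% of distal summits (right), black where the adjusted p is under 0.05. The composite GATA and E-box motif has odds ratios of 16.6, 3.45 and 15.2 from left to right.

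The last comparison asked whether summits called in one library fall near the genes of one cell type. Near hepatoblast genes lay 16 of the 5571 summits of library 1 alone, against 41 of 43919 shared ones (odds ratio 3.14, exact test, adjusted p = 0.0034), and 19 of the 3241 summits of library 2 alone, against 42 of 42352 (6.02, adjusted p = 4.24e-07). Stellate genes were also more frequent beside the summits of each library alone (odds ratio 9.33 and 16, exact test, adjusted p = 0.0034 and 0.00161). These rest on few summits, 6 alone against 5 shared in library 1 and 5 against 4 in library 2. Neuronal (5.20, exact test, adjusted p = 0.000532) and muscle genes (5.64, adjusted p = 0.00715) were so in library 1, and mature hepatocyte genes (4.95, adjusted p = 0.0055) in library 2. The red cell membrane list (0.466, exact test, adjusted p = 0.0502) did not pass in library 1, nor did the other 13 lists there or the other 15 in library 2. Each test was adjusted over 18 lists and compares these 2 libraries, not conditions. Summits called in one library alone had lower signal than shared ones, and the tests were not matched on signal. A difference between cell types therefore cannot be told from a difference in peak strength. Leaving out summits with a peak in the less strict list of the other library kept 404 summits of library 1 and 118 of library 2, a number at which all 7 calls ended with little power (exact test, adjusted p = 1). The share near neuronal genes in library 1 was then 0.248%, against 0.233% before, and the shares of all the other ended calls were 0. With 1 summit per region the hepatoblast and muscle calls of library 1 (exact test, adjusted p = 0.195 and 0.213) and the mature hepatocyte and stellate calls of library 2 (0.168 and 0.150) ended.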

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

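The tests of depth and enrichment in library 1 were chosen after the result was seen, and the permutation of merged regions in the rank test replaced one of gene labels after its first result was seen. A signal in data that the comparisons did not use was found in the authors' ranked list of the pool, where 61264 summits meet the IDR threshold and 179 of them are missing from the thresholded list of 61085. Of these, 49 (27.4%) lie on unplaced or unlocalized scaffolds, which leaves 130 in 55 chromosomal regions that scaffolds do not account for. Repeated sequence fits the chromosomal ones, whose median repeat-masked share was 31% against 8.26% in 2000 thresholded regions (difference 22.8 points, permutation p = 1e-05, the smallest possible), with 18 regions (32.7%) at least 50% repeat against 3.70%. Copied mitochondrial sequence does not account for the set, since 1 of the 55 regions (1.82%) shared 20% or more of its 31-mers with the mitochondrial genome. That region, chromosome 1, 24611586 to 24616161, nevertheless had 98.8% and held 15 of the 130 missing chromosomal summits. It also had the highest −log10 p of the list (14949.8 against 14371.8 in the thresholded list). No header states a filter on such regions, and no biological explanation was tested.

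Library 1 had more thresholded summits than library 2, 49490 against 45593. Over matched summits its −log10 p was 1.41 times that of library 2, which fits deeper sequencing, and its signal was 1.06 times, which fits stronger enrichment. Both explanations stay open because read counts were not analysed here. A different mix of erythroid and hepatocyte cells was tested by the shift in signal rank, library 1 minus library 2. For summits near erythroid genes (242) it exceeded that near hepatocyte genes (49) by 0.755 percentile points (95% interval −1.64 to 3.33, permutation p = 0.449). The prediction in advance took a difference within 1 percentile point of none as evidence against a different mix. The interval reaches past that bound on both sides, so this test left the question open.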

How the results depend on the processing

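The alternatives with 1 summit per region, merged regions and GC-matched strength were chosen after the data were seen. Across single lists and motifs, 696 values kept their call or stayed without one, some of the latter on the other side of no difference, 78 lost the call, 32 gained one and 16 reversed with a call before or after. Of summary values, 67 stayed and 70 moved. The erythroid, red cell membrane, megakaryocyte and olfactory distal calls held in every alternative run. For each change below the cause was not tested. Unknown depth limits all peak numbers.

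Summits numbered 103187 (replicated), 104799 (pseudoreplicated), 55373 (IDR 0.01), 29314 (merged) and 45593 to 49490 (each library alone), covering 33.7, 34.1 and 19.7 Mb in the first 3 and 16.2 to 17.4 Mb alone. Sharing for library 1 was 77.4% within 100 bp, 92.1% among the 20000 strongest and 84.2% of merged regions; for library 2, 84.1% within 100 bp, 87.0% pseudoreplicated and 89.8% of merged regions. With −log10 p, rho was 0.971 and r 0.965, and in ranked lists 0.935 and 0.946.

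Promoter, exon, intron and intergenic shares were 45.3, 3.77, 33.0 and 17.9% at 500 bp, 59.5, 1.95, 24 and 14.6% at 2500 bp, 39.0, 3.76, 36.2 and 21% in replicated peaks, 41.8, 2.93, 35.5 and 19.7% with 1 summit per region, and 59.7 to 61.0, 2.17 to 2.18, 23.2 to 24.1 and 13.7 to 14.0% in each library alone. The conservative list gave an exon share of 2.58%.

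In replicated peaks, promoter shares reversed for hepatoblast (90.6%), endothelial (70%) and bile duct genes (62.5%), and 4 lists were lower (9 in the main analysis). Distal lists higher numbered 5 without territory matching and 4 with promoter matching (8), and lists lower 1 (2) with all distal summits within 50000 bp counted for each start, promoter matching, conservative or replicated peaks, 1 summit per region, and 1 to 2 in each library alone.

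Without GC matching, distal odds ratios reversed for FOXA (0.988) and MEF2 (0.804), and promoter ones for GATA (0.383), AP-1 (0.708), HNF4 (0.518), FOXA (0.390), NFY (0.910), MEF2 (0.359) and POU (0.664). The promoter PU.1 ratio reversed within 200 bp (0.976). Motifs lower at distal summits (1) numbered 4 without GC matching, 2 within 50 bp, in the conservative list and with 1 summit per region, and 1 to 2 in each library alone; at promoters (3), 11 without GC matching and 1 in replicated peaks. With 1 summit per region the strength ratios of AP-1 (0.997), CTCF (0.271) and FOXA (0.733) reversed and 3 motifs were higher (11), against 7 to 9 higher and 0 to 1 lower (3) in each library alone. Lists higher near library-only summits fell from 4 (library 1) and 3 (library 2) to 0 without summits in the other's pseudoreplicated list, where only 404 and 118 summits remain, and to 2 and 1 with 1 summit per region.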

Other observations

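The gene families below were chosen after the data had been seen, and in the test of motifs near gene lists, whose predictions came first, the permutation of merged regions and the use of the interval in the verdict replaced a permutation of gene labels after its result was seen. Families of broadly used genes were open at their promoters: 77 of 80 ribosomal protein genes (Fisher's exact test, adjusted p = 2.38e-18 over 12 families), 63 of 67 clustered histone genes (7.54e-14), 37 of 40 proteasome subunits (3.95e-08) and 310 of 394 Zfp zinc finger genes (5.78e-29) had a promoter summit. Hox genes, which pattern the body axis, had none in 39 (1.10e-12), keratins 1 in 53 (4.57e-15), vomeronasal receptors 1 in 330 (2.76e-101), cytochromes P450 12 in 100 (6.45e-16), collagens 6 in 45 (13.3%, with 6.67% in library 1 and 4.44% in library 2, 2.45e-07), potassium channels 19 in 81 (23.5%, with 11.1% and 13.6%, 5.39e-07) and interleukins and their receptors 18 in 82 (1.13e-07). Solute carriers did not differ from other genes (196 of 371, 0.565). Family members that lie side by side, such as keratins on chromosome 15, were counted as independent genes, so these p-values can be too small.

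Solute carriers had 1.28 times the distal summits of matched random sets (permutation test, adjusted p = 0.0219), led by Slc22a23 with 18, Slc20a1 and Slc16a1, which carry phosphate and lactate, with 13 each, and Slc30a10, a manganese exporter, with 12. Clustered histones had 2.39 times (0.00888). Cytochromes P450 (0.145 times, 0.00012), vomeronasal receptors (0.0838 times, 0.00012), keratins (0.231 times, 0.00888) and Hox genes (0.159 times, 0.0246) had fewer. Ribosomal proteins, Zfp genes, collagens, proteasome subunits, potassium channels and interleukins did not pass (0.183, 0.191, 0.373, 0.199, 0.0799 and 0.566).

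If the pooled list mixes elements of erythroid and hepatocyte cells, distal summits near the genes of each should differ in motifs. Distal summits near erythroid list genes (367 in 238 regions, from the erythroid, red cell membrane, heme and globin lists) were compared with those near hepatocyte list genes (136 in 80 regions, from the hepatoblast, coagulation and mature hepatocyte lists) by permuting the labels of merged regions, adjusted over 22 motifs, since the permutation of gene labels gave small p-values to motifs found in a single summit. GATA sites were more frequent near erythroid genes, 59.7% against 42.6% (17.0 points, 95% interval over resampled genes 8.11 to 26.3, permutation adjusted p = 0.0127), and so was the composite motif, 11.2% against 2.94% (8.23 points, permutation adjusted p = 0.0347). Of the other distal summits, 54.7% had a GATA site and 7.80% the composite. For both motifs the share near erythroid genes lay closer to these values than the share near hepatocyte genes did. HNF4 sites were in none of the erythroid and 4.41% of the hepatocyte summits (−4.41 points, 95% interval −8.66 to −0.885, permutation adjusted p = 0.0127), and FOXA sites in 4.36% against 11.8% (−7.41 points, 95% interval −14.4 to −1.43, permutation adjusted p = 0.0202). CEBP sites did not differ in the predicted direction (0.545 points, 95% interval 0 to 1.40, permutation p = 0.213). These tests fit a mixture for GATA, HNF4 and FOXA. For CEBP the prediction in advance took a difference of 0 or the other way as evidence against it, but that bound was wrong for so rare a site, which is in 0.363% of other distal summits, so that none among 136 decides nothing, and CEBP stays open. The gene lists are small and peaks were not assigned to cells.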
